A study of Mus musculus with 9 samples.

How the data were processed

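RNA was measured in 9 libraries of cultured mouse cells, 3 from each of 3 cell types named AFSC, ALSC and ABSC. The labels give the strain as Sv129 x GOF/GFP F1. Per the labels' protocols, messenger RNA was captured with poly-T beads and made into libraries with a NEBNext Ultra kit, which does not mark the strand. The series record gives paired-end reads of 150 bases on a HiSeq X10, while the labels' protocols name an older HiSeq model, so the instrument is uncertain. Per the labels' protocols, 1 RNA kit served all collected cells and another is named for ALSC, so the RNA kit may differ with the cell type. The passage ranges do not overlap beyond their ends: 15 to 20 for AFSC, 20 to 25 for ALSC and 25 to 30 for ABSC. Passage and cell type therefore cannot be told apart.

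The deposited values are raw read counts per gene and library. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. The notes name the genome build mm9. The deposited count table itself carries gene coordinates, and of its 54532 Ensembl genes 54409 were found by ID in a GRCm38 annotation (GENCODE M21), 53499 of them with the same chromosome, start and end (98.33% of the shared IDs). Coordinates given here are therefore those of the table, read as GRCm38. The table held 54878 entries. The 346 loci without an Ensembl ID or symbol carried 0.208% to 0.227% of the counts in each library and were left out of the tests. Because the kit is unstranded, reads from overlapping genes cannot be told apart; of 114 genes chosen by the naming rule and tested, 20 overlap another tested gene.

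Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16178 genes, 13527 of them protein coding. Libraries were scaled by TMM, with factors between 0.963 and 1.06. All 9 libraries entered 1 fit with group means, robust quasi-likelihood dispersions and 6 residual degrees of freedom. The pooled biological coefficient of variation was 0.147. Each of the 3 pairs of groups was compared by a 2-sided quasi-likelihood F test, and a further F test asked for any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is said to have risen or fallen where the adjusted p was under 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute change over the square root of F. Levels are CPM, library-scaled counts computed from the deposited counts with the TMM factors, given as mean ± SD with n = 3. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. That floor and the per-library floors, 0.138 to 0.157 CPM, cover counting error only, since the reads carry no molecular identifiers.

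The comparisons, tests, alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule selects 21 key genes whatever their result, up to 4 called members of each list with the largest changes among members at 1 CPM or more, and the 6 genes with the largest rise and the 6 with the largest fall among genes at 10 CPM or more. From these, the text prefers genes whose call held when each library was left out in turn. Not every selected gene is therefore given in every comparison, and a gene left out may still have been called. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over 72 tests of 24 lists in 3 comparisons. Camera with an estimated correlation and fry were run beside it. Of the other 2 lists, the 2-cell-like list had 0 genes tested and the Hox cluster list had 1, so neither was tested as a list. Counts of called members are given over all genes tested, and for many lists also adjusted over the list alone. ABSC and ALSC were both compared with the same 3 AFSC libraries, so 20 simulations without any effect were run. Each drew all 9 libraries, the controls included, from the AFSC means at the spread of the fit without a block. Both unchanged groups were then compared with the same 3 simulated controls for overlap, correlation and covariance.

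The labels number the libraries 1 to 3 in each group. The labels do not say what a number stands for, so the pairing was checked from the data, by correlating the deviations of libraries from their group means. Libraries numbered 1 correlated at 0.464 to 0.554, libraries numbered 2 at 0.197 to 0.287, and libraries numbered 3 at 0.224 to 0.356. Every same-number correlation was above 0.1, the threshold used to take the numbers as pairing the libraries. That threshold decides little, because the deviations of a group cancel out. A shared deviation of number 1 alone therefore makes the correlations among numbers 2 and 3 positive. Numbers 2 and 3 also correlated with each other, at 0.221 to 0.273, and number 1 with numbers 2 or 3 at -0.426 to -0.304. The values thus show number 1 apart from the others in each group. They do not show that number 2 pairs with number 2 or number 3 with number 3. The fit planned as main has no block, and the fit with the replicate number as a block was the other fit fixed in advance, with a coefficient of variation of 0.0717. The labels also do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples. A chi-square test of counts over genes found no identical pair of libraries within a group. Chi-square over its degrees of freedom was 2.10 to 4.23 for numbers 2 and 3, and 12.7 to 25.9 for pairs with number 1. Numbers 2 and 3 were thus the closest pair in every group, so the 3 libraries of a group may not be equally independent.

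The fit was tested on simulated data with 200 genes changed. In the simulation of ABSC against AFSC, with 15876 genes tested, 35.8% of the genes changed 1.5-fold, 61.2% of those changed 2-fold and 84.9% of those changed 4-fold were recovered, and 0.0447% of unchanged genes were called. For ALSC against AFSC, with 15907 genes tested, the shares were 38.8%, 59.7% and 92.4%, with 0.0700% of unchanged genes called. For ABSC against ALSC, with 15902 genes tested, they were 32.8%, 53.7% and 84.9%, with 0.0573%. The simulated libraries varied independently, without the deviation that the libraries of number 1 share, and only 200 genes changed. These shares therefore need not carry over to the real libraries. Alternatives were DESeq2 1.42.0, RLE size factors, library size only, no filter, a filter of 1 CPM in 3 libraries, the 6 libraries of each pair alone, a test against a 2-fold change, protein-coding genes only, the replicate block, and leaving out each library in turn. Chosen after seeing the data were a fit of libraries 2 and 3 only, a block of number 1 against the other numbers, and the removal of each library's GC trend together with the replicate block. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.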

Results

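The transcriptomes of 3 related mouse stem cell types were measured, with 3 libraries of each. AFSC resemble epiblast stem cells, the pluripotent cells of the embryo after implantation, and were derived from blastocysts in Activin A and bFGF. ALSC and ABSC were made from AFSC by more than 5 passages in another medium. ABSC, described by the labels as resembling trophoblast stem cells, grew in Activin A and BMP4. ALSC are taken here to have grown in Activin A and leukaemia inhibitory factor (LIF), although the protocol gives that recipe under the abbreviation of the ABSC medium. The series title concerns progenitor cells held by Activin A together with BMP4, so the comparisons ask what each medium changed against AFSC and how ABSC and ALSC differ. Total counts ran from 18978651 in ALSC 2 to 21578737 in AFSC 3.

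The pluripotency factor Pou5f1 was abundant in all 3 cell types, at 1226 ± 42.4 CPM in ABSC, 1074 ± 42.5 CPM in AFSC and 935 ± 30.6 CPM in ALSC. The Y-linked gene Ddx3y was present in every library, at 91.0 to 144 CPM, and Xist stayed at 0.246 to 0.898 CPM. The 3 leading principal components held 34.9%, 22.6% and 20.0% of the variance, and both the cell type and the library number separated libraries. Libraries numbered 1 had less Eomes (log2 difference -1.48) and Lefty1 (-0.84) than numbers 2 and 3, and more Vegfa (1.55) and Chac1 (2.45). Evx1 was at -1.29 in ABSC 1 but 0.47 in ALSC 1, and Cdx2 at -2.76 in ABSC 1, the group where it was above the floor. A test of any difference among the 3 cell types called 2395 of 16178 genes, and 5992 with the replicate block. That count was 1433 without AFSC 2, 1431 without AFSC 3, 1395 without ABSC 2 and 1525 without ABSC 3.

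**Figure D1:**
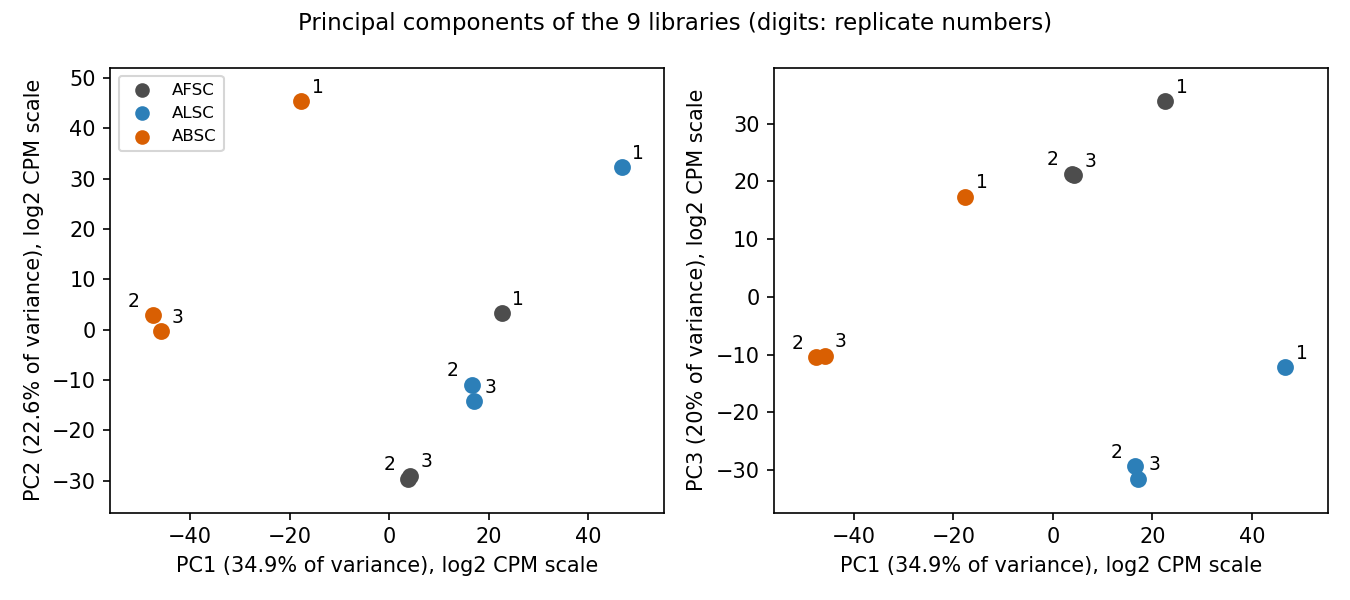
Principal components of log2 CPM, with component 1 against component 2 and component 1 against component 3. Each point is 1 library, coloured by cell type and labelled by its number; the components hold 34.9%, 22.6% and 20.0% of the variance, and libraries 2 and 3 of each type lie close together.

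The comparison of ABSC with AFSC asks what BMP4 in place of bFGF, with Activin A kept, goes with. Hand1, a transcription factor of trophoblast giant cells and extraembryonic mesoderm (chromosome 11, 57828705 to 57832818), stood at 213 ± 28.7 CPM in ABSC and 0.240 ± 0.119 CPM in AFSC (log2 fold change 9.75, SE 0.22, edgeR adjusted p = 9.17e-09). Id1, a direct BMP target (chromosome 2, 152736251 to 152737410), stood at 59.8 ± 7.60 CPM against 2.08 ± 0.936 CPM (4.85, SE 0.42, edgeR adjusted p = 0.000121). Fgf5, a marker of the epiblast after implantation (chromosome 5, 98254184 to 98277030), was at 16.3 ± 2.52 CPM against 189 ± 4.76 CPM (-3.53, SE 0.14, edgeR adjusted p = 1.25e-06). Lefty1, a Nodal target (chromosome 1, 180935022 to 180938400), was at 16.1 ± 9.84 CPM against 130 ± 35.6 CPM (-3.02, SE 0.45, edgeR adjusted p = 0.00366). Of the BMP target list, 8 of 11 genes tested rose and 0 fell (10 and 0 adjusted over the list alone), including Id2 (2.20), Msx1 (4.12) and Msx2 (3.09). The list rose as a whole (camera adjusted p = 7.13e-09), also with an estimated correlation (adjusted p = 0.0286), but the replicate block and an estimated correlation together gave an adjusted p of 0.157. Of the Activin and Nodal target list, Tdgf1 rose (0.49), and Lefty2 fell (-1.29) with Lefty1 and 1 other gene, while the list as a whole was not called (camera adjusted p = 0.200).

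Trophoblast and streak genes of ABSC did not move as single blocks. Cdx2, a regulator of trophoblast stem cells (chromosome 5, 147300805 to 147307270), was at 4.45 ± 3.13 CPM in ABSC and 0.126 CPM in AFSC (log2 fold change 5.04, SE 0.93, edgeR adjusted p = 0.00839). Its level was 0.835 CPM in ABSC 1, 6.43 CPM in ABSC 2 and 6.07 CPM in ABSC 3, and without AFSC 3 the fold change was 5.80 (edgeR adjusted p = 0.0337). Of 20 alternative settings 2 lost the call, 1 of them the fit without a filter on low counts. The trophoblast stem cell list had 4 of 12 tested genes higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0335). That call was lost with the replicate block (camera adjusted p = 0.114) and at adjusted p = 0.200 with an estimated correlation. Elf5 and Gata3 stayed below 1 CPM in each group mean and were not tested. Of the differentiated trophoblast list, 3 of 14 genes were tested, and Hand1 was the 1 called; the placental hormone genes Prl3d1 and Prl3b1 and the spongiotrophoblast gene Tpbpa had 0 counts in all 9 libraries. Evx1 of the posterior streak (chromosome 6, 52313498 to 52318378), which overlaps its antisense gene Evx1os, rose to 49.1 ± 20.9 CPM from 1.14 CPM (5.41, edgeR adjusted p = 3.57e-05). Foxa2 of the anterior streak and endoderm (chromosome 2, 148042877 to 148046969) fell (-5.64, edgeR adjusted p = 4.19e-06), as did Lhx1 (-4.84). T did not pass (0.82, edgeR adjusted p = 0.0587), nor did Eomes, at 117 ± 68.8 CPM against 122 ± 38.1 CPM (-0.07, edgeR adjusted p = 0.973). The primitive streak list had 1 of 13 tested genes higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.0178). That call was lost at adjusted p = 0.438 with an estimated correlation and at 0.309 without ABSC 1.

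Part of the markers of the primed epiblast state fell in ABSC and part of the genes of the naive state rose. The primed epiblast list had 6 of 12 tested genes lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 6.45e-05; adjusted p = 0.160 with an estimated correlation). The naive pluripotency list had 3 of 10 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.000646; adjusted p = 0.160 with an estimated correlation). Among these, Nr5a2 rose (3.11), Klf5 rose (0.85), and Dppa3, with 0 counts in AFSC and 1.89 ± 0.187 CPM in ABSC, was at least 39.0-fold higher. Zfp42 was at 0.471 CPM in ABSC and not tested, and Klf4 was not called (edgeR adjusted p = 0.731). The core pluripotency list had 4 of 12 higher, Gdf3 (3.43) and Nanog among them, and 1 lower, Sox2 (4 and 2 adjusted over the list alone; camera adjusted p = 0.0996, and 0.0397 without ABSC 1). Leaving out 1 library at a time gave Nanog 0.30 to 0.47, with the call lost in 6 fits. For Sox2 it gave -0.74 to -0.54, with the call lost in 1 fit. The LIF and STAT3 target list had 4 of 11 higher and 0 lower (5 and 0 adjusted over the list alone), with Lifr at 1.17 and Pim1 at 0.95 (camera adjusted p = 0.0133; adjusted p = 0.160 with an estimated correlation). The neural ectoderm list had 1 of 5 lower (2 adjusted over the list alone; camera adjusted p = 0.0126; adjusted p = 0.254 with an estimated correlation). The surface ectoderm and amnion list had 1 of 7 higher, Grhl2 (0.74), and 3 higher adjusted over the list alone (camera adjusted p = 0.0361, and 0.0715 without ABSC 2; adjusted p = 0.200 with an estimated correlation).

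The other lists were not called by camera in ABSC against AFSC in the fit without a block, although single members were. Of the lists not called by camera, fry called the differentiated trophoblast (adjusted p = 3.09e-05), mesoderm (0.0249) and germ cell (0.0150) lists. It also called the Activin and Nodal target (0.0421), epithelial (0.0187), and stress and p53 (0.0187) lists. Of the mesoderm list Tbx20 rose (2.45) and 1 gene fell. The primitive endoderm list had 2 genes higher, Col4a2 (1.49) and Col4a1, which overlap each other, and 1 lower, Sox17 (3 and 4 adjusted over the list alone), although its median was -0.42. Sox17 stood at -4.97 to -3.23 when 1 library was left out, and its call held in each such fit. Of 21 alternative settings 1 lost it. Of the WNT target list 3 genes fell, with Lef1 at -1.19, and 0 rose (3 fell and 2 rose adjusted over the list alone). Of the imprinted list Plagl1 (1.74) and Igf2r (0.64) rose and Meg3 fell (-0.56). The mesenchymal list had 2 of 11 higher, with Fn1 at 0.66, and 2 lower. Acta2 of the fibroblast list rose (2.34), Mcm6 of the proliferation list rose (0.34), and Mdm2 of the stress and p53 list fell (-0.74). Of the epithelial list, Cdh1 stood at 875 ± 88.2 CPM against 885 CPM and was not called. The glycolysis list was called lower with the replicate block (camera adjusted p = 0.00681) and without ABSC 1 (0.00941); with the block it was lost at adjusted p = 0.542 with an estimated correlation. The oxidative phosphorylation list and the FGF and ERK target list had 0 genes called (0 higher and 3 lower, and 1 and 3, with the replicate block), and the germ cell list 1 in each direction. The median and the mean of the log2 changes had opposite signs for the differentiated trophoblast (-0.17 and 2.81), mesoderm (-0.03 and 0.26), germ cell (-0.08 and 1.25), fibroblast (-0.25 and 0.17) and WNT target (0.05 and -0.47) lists, and camera took the sign of the mean in each. With Dppa3 at its bound the germ cell median stayed at -0.08 and the mean was 0.75. Over all genes, 644 rose and 647 fell (1291), of which 214 and 322 changed at least 2-fold. Tmod1 (4.70, overlapping Tstd2) and Stk32a (3.65) were among the largest rises of genes at 10 CPM or more, and Glyatl3 (-3.68) and Nmral1 (-2.64) among the largest falls. The total was 3132 with the replicate block, 686 without AFSC 2, 667 without AFSC 3, 685 without ABSC 2 and 746 without ABSC 3.

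**Figure D2:**
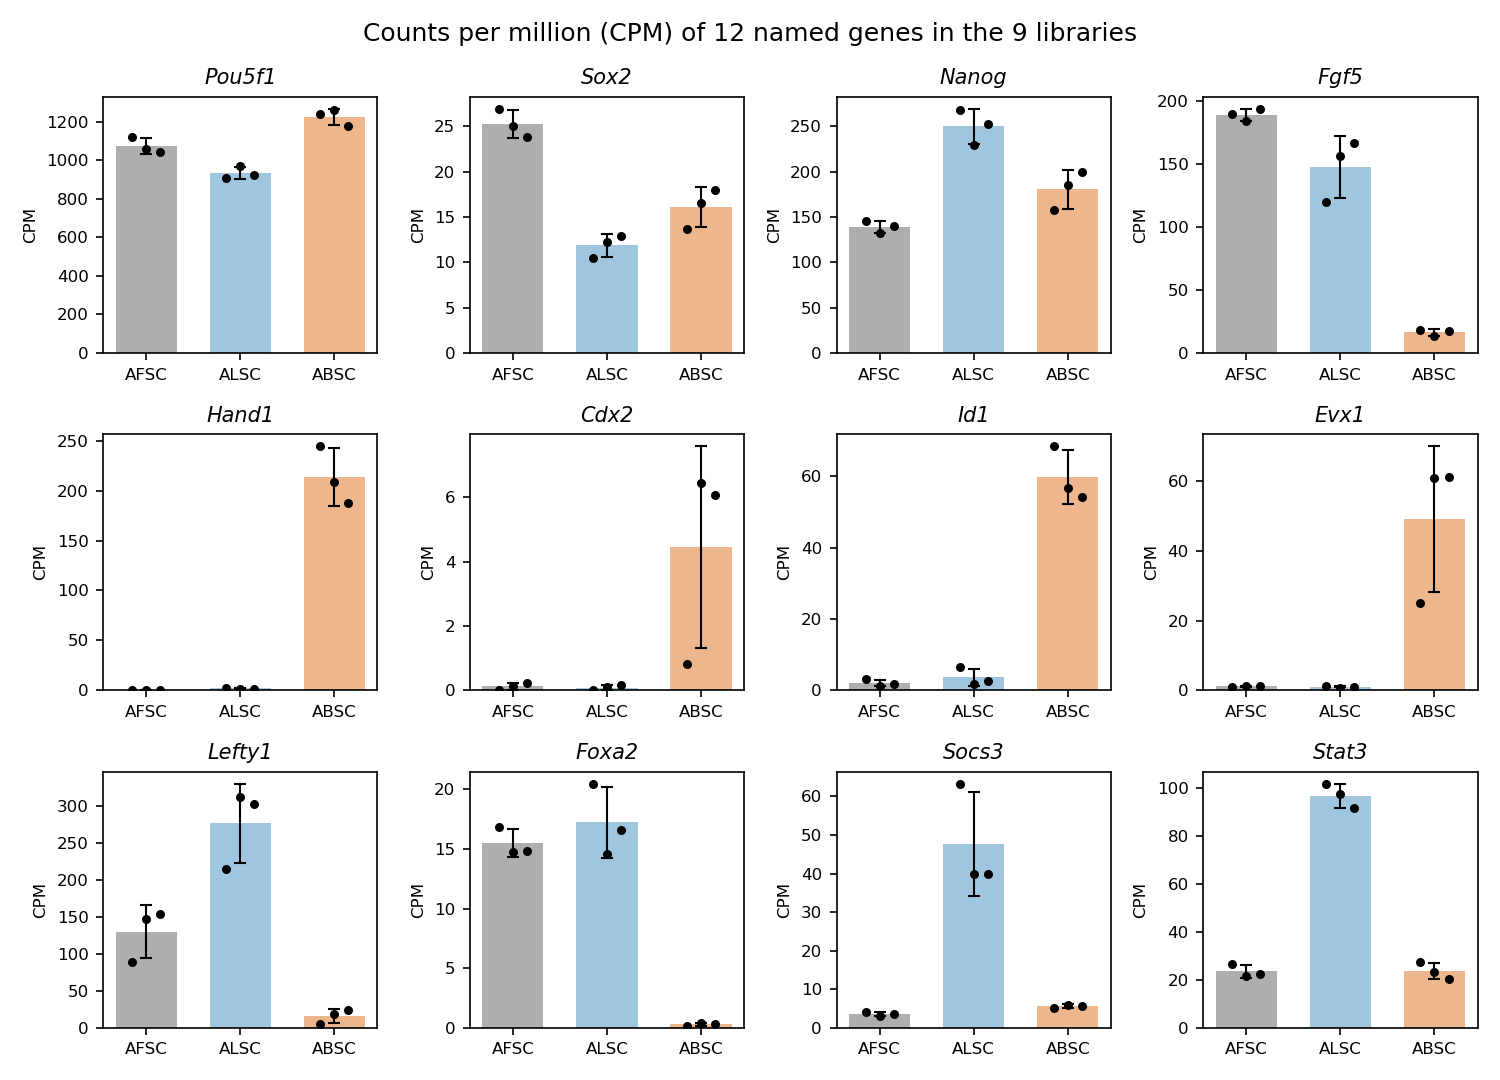
Levels of 12 genes, in CPM, in AFSC, ALSC and ABSC. Bars show the mean, error bars the SD and points the 3 libraries; Hand1 averages 213 CPM in ABSC and 0.240 CPM in AFSC, and Socs3 47.7 CPM in ALSC and 3.60 CPM in AFSC.

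The comparison of ALSC with AFSC asks what LIF in place of bFGF, with Activin A kept, goes with. Socs3, a feedback inhibitor that STAT3 induces (chromosome 11, 117966079 to 117970047), stood at 47.7 ± 13.5 CPM in ALSC and 3.60 ± 0.435 CPM in AFSC (log2 fold change 3.73, SE 0.21, edgeR adjusted p = 5.27e-05). Stat3 itself (chromosome 11, 100885098 to 100939540) was at 96.6 ± 5.03 CPM against 23.6 ± 2.63 CPM (2.04, SE 0.12, edgeR adjusted p = 5.27e-05). Tfcp2l1, a naive-state factor downstream of LIF (chromosome 1, 118627945 to 118685168), was at 109 ± 36.5 CPM against 21.3 ± 3.49 CPM (2.35, SE 0.25, edgeR adjusted p = 0.000878). Nanog rose to 250 ± 19.3 CPM from 139 ± 6.54 CPM (0.84, edgeR adjusted p = 0.000881), and Sox2 fell to 11.9 ± 1.29 CPM from 25.3 ± 1.56 CPM (-1.09, edgeR adjusted p = 0.00155). Of the LIF and STAT3 target list, 5 of 11 genes tested rose and 0 fell (5 and 0 adjusted over the list alone), with Bcl3 at 2.30. The list was called (camera adjusted p = 0.000308), but its call was lost at adjusted p = 0.0974 with an estimated correlation. Klf4, a naive-state target of STAT3, was at 2.41 CPM against 2.26 CPM (edgeR adjusted p = 0.874).

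Pluripotency genes moved both ways in ALSC. The core pluripotency list had 3 of 12 tested genes higher, with Gdf3 at 4.20, and 3 lower (camera adjusted p = 0.805). The naive list had 3 of 10 higher and 2 lower, Fgf4 among them (-0.66; camera adjusted p = 0.291). The primed epiblast list had 4 of 12 lower and 0 higher (6 and 0 adjusted over the list alone), with Pou3f1 at -1.40 and Sall2 at -0.67 (camera adjusted p = 0.0106; adjusted p = 0.272 with an estimated correlation). Fgf5 was not called, at 147 ± 24.3 CPM (-0.36, edgeR adjusted p = 0.125), nor was Otx2 (0.01, edgeR adjusted p = 0.964). The germ cell list had 2 of 6 higher and 0 lower (2 and 0 adjusted over the list alone), with Kit at 1.02 (camera adjusted p = 0.0280, 0.0678 with the replicate block and 0.0570 without AFSC 1; adjusted p = 0.200 with an estimated correlation). The primitive streak list had 3 of 13 higher and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.0329). Its call was lost at 0.0607 without ALSC 3 and at 0.0509 with library size only, and at adjusted p = 0.505 with an estimated correlation.

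Targets of the FGF and ERK pathway were lower for Dusp6, at 220 ± 10.4 CPM against 339 CPM (-0.62, edgeR adjusted p = 0.00112), and the list had 2 of 12 lower. That list was not called (camera adjusted p = 0.0810), but was with the replicate block (0.0404), without AFSC 1 (0.0251), without ALSC 2 (0.0128) and without ALSC 3 (0.0224). With the block it was lost at adjusted p = 0.666 with an estimated correlation. The stress and p53 target list had 4 of 13 lower and 0 higher (7 and 0 adjusted over the list alone), with Mdm2 at -1.20, Phlda3 at -0.59 and Sesn2 at -0.40 (camera adjusted p = 0.00642; adjusted p = 0.160 with an estimated correlation). Of the BMP target list Id2 fell (-1.98) and 0 genes rose, while Id1 was not called (edgeR adjusted p = 0.296; camera adjusted p = 0.448). Of the Activin and Nodal target list Lefty2 (1.33) and Tdgf1 (0.75) rose and 1 gene fell, while Lefty1, at 277 ± 53.9 CPM, was not called (1.09, edgeR adjusted p = 0.155; camera adjusted p = 0.356). Of the differentiated trophoblast list, Hand1 rose to 2.08 ± 0.388 CPM (3.08), far below its 213 CPM in ABSC, and the trophoblast stem cell list had 1 of 12 higher and 2 lower.

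The remaining lists were not called by camera in ALSC against AFSC. Of all lists not called by camera here, fry called the naive pluripotency (adjusted p = 0.0281), differentiated trophoblast (0.00845) and mesoderm (0.00647) lists. It also called the surface ectoderm and amnion (0.0220), BMP target (0.0140) and epithelial (0.00845) lists. The primitive streak list, which camera had called (camera adjusted p = 0.0329), was not called by fry (adjusted p = 0.108). Grhl2 (-0.58) of the surface ectoderm list, Lef1 (-1.40) of the WNT list, Rab25 (-0.92) of the epithelial list, and Twist1 (-2.87) of the mesoderm and mesenchymal lists fell. In the same lists 1 surface ectoderm, 1 WNT and 2 mesenchymal genes rose, and the WNT list had 4 higher and 2 lower adjusted over the list alone. Of the imprinted list Rian rose (0.42) and Snrpn fell (-0.45, overlapping Gm38393), with 7 higher and 1 lower adjusted over the list alone. The neural ectoderm list was called without ALSC 1 (camera adjusted p = 0.0383) and the epithelial list without AFSC 3 (0.0465). The primitive endoderm, fibroblast, glycolysis and oxidative phosphorylation lists had 0 genes called. With the replicate block they had 3 higher and 2 lower, 1 and 1, 2 and 3, and 0 and 1 in that order. The mesoderm list had 0 higher and 1 lower (0 and 3 adjusted over the list alone), and the proliferation list 2 higher and 1 lower. Median and mean had opposite signs for the differentiated trophoblast (-0.39 and 0.70), mesoderm (0.15 and -0.41), mesenchymal (0.09 and -0.07), fibroblast (0.13 and -0.04) and glycolysis (-0.02 and 0.01) lists; camera took the sign of the median for the mesenchymal and glycolysis lists and that of the mean for the others. Over all genes, 573 rose and 566 fell (1139), of which 224 and 146 changed at least 2-fold. With library size as the only scaling 666 rose and 444 fell, so the share higher was 60.0% in place of 50.3%. Apobec3 (3.99, overlapping Cbx7) and Tfeb (3.10) were among the largest rises of genes at 10 CPM or more, and Klhl4 (-2.38), Psors1c2 (-2.11), Slc4a11 (-1.84) and Mllt10 (-1.82, overlapping Dnajc1) among the largest falls. The total was 3590 with the replicate block, 349 without AFSC 2, 345 without AFSC 3, 642 without ALSC 2 and 559 without ALSC 3.

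**Figure D3:**
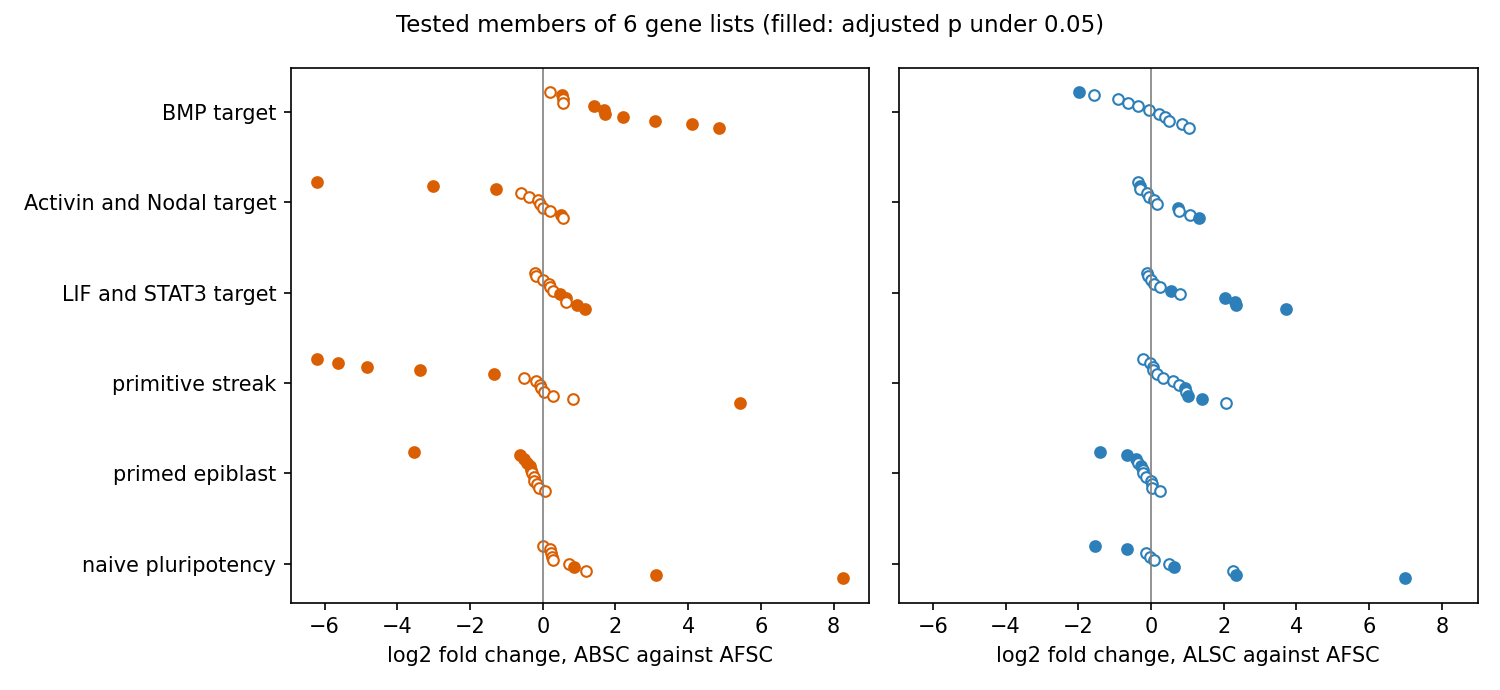
Log2 fold changes of the tested members of 6 gene lists, in ABSC against AFSC and in ALSC against AFSC. Each point is 1 gene and filled points have an edgeR adjusted p under 0.05; 8 of 11 BMP target genes are higher in ABSC and 5 of 11 LIF and STAT3 target genes are higher in ALSC.

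The direct comparison of ABSC with ALSC asks how cells in BMP4 differ from cells in LIF with Activin A in both. BMP targets were higher in ABSC for Id1 (log2 fold change 3.99, SE 0.39, edgeR adjusted p = 0.000235) and Id2 (4.18), where Id1 differed by 4.67 without ALSC 1. Hand1 differed by 6.67 (SE 0.17, edgeR adjusted p = 2.99e-08) and Cdx2 by 5.64 (SE 1.00, edgeR adjusted p = 0.00615), by 5.05 without ALSC 1 and by 6.33 without ALSC 3. LIF targets were lower for Socs3 (-3.08, SE 0.20, edgeR adjusted p = 1.42e-05), Bcl3 (-2.50), Tfcp2l1 (-2.07) and Stat3 (-2.03). Lefty1 (-4.11, SE 0.47, edgeR adjusted p = 0.000793), Lefty2 (-2.62) and the streak genes Foxa2 (-5.79) and Gsc (-4.40) were lower in ABSC, and Evx1 was higher (5.45). Of the BMP target list, 8 of 11 genes were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.06e-07), also with an estimated correlation (adjusted p = 0.0286) but not with the block added to it (0.157). Across the 72 list tests, camera called 18, several of them for the same list in more than 1 comparison. The BMP target list in this comparison and against AFSC gave the 2 calls that hold with an estimated correlation. With the replicate block and an estimated correlation together camera called 0 of the tests, the lowest adjusted p being 0.157. The primitive streak list had 6 of 13 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.000646; adjusted p = 0.276 with an estimated correlation).

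Part of the epithelial and trophoblast genes also stood higher in ABSC than in ALSC. The epithelial list had 5 of 12 higher and 1 lower (6 and 1 adjusted over the list alone), with Rab25 at 1.08 and Ocln at 1.07 (camera adjusted p = 0.00894; adjusted p = 0.160 with an estimated correlation). The lower gene was Cldn3, at -2.005 to -1.399 when 1 library was left out, with its call lost in 2 such fits. The surface ectoderm and amnion list had 1 of 7 higher, Grhl2 (1.32), and 2 adjusted over the list alone (camera adjusted p = 0.0168; adjusted p = 0.174 with an estimated correlation). The trophoblast stem cell list had 6 of 12 higher, Cdx2 among them, and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0356, and 0.194 with the replicate block; adjusted p = 0.200 with an estimated correlation). Of the mesenchymal list Zeb2 (-1.74), Zeb1 (-1.44) and Cdh2 (-0.82) were lower and 2 genes, Tgfbi and Vim, higher (3 and 4 adjusted over the list alone). When 1 library was left out, Tgfbi stood at 2.214 to 3.149 and Vim at 0.457 to 0.668. Each lost its call in 2 such fits. The list was not called (camera adjusted p = 0.744). Pou5f1 was higher in ABSC than in ALSC (0.39, SE 0.05, edgeR adjusted p = 0.00110) and Nanog lower (-0.47, edgeR adjusted p = 0.00956). Nr5a2 (4.65) and Fgf4 (0.88) of the naive list were higher; that list was not called (camera adjusted p = 0.0917), but was without AFSC 3 (0.0459), ALSC 2 (0.0180), ALSC 3 (0.0172) or ABSC 1 (0.00990). Of the primed list, Fgf5 (-3.17) and Otx2 (-0.35) were lower and Pou3f1 (0.88) higher.

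Other lists were not called by camera between ABSC and ALSC. Of the lists not called by camera, fry called the naive pluripotency (adjusted p = 0.00319), primed epiblast (0.0249), differentiated trophoblast (0.000125) and mesoderm (0.000651) lists. It also called the germ cell (0.0120), Activin and Nodal (0.00656), LIF and STAT3 (0.000781), WNT (0.00855), and stress and p53 (0.00844) lists. Kit of the germ cell list (-1.69) and Pdk1 of the glycolysis list (-0.46) were lower in ABSC, and Tbx20 of the mesoderm list (3.32), Dusp6 of the FGF and ERK list (0.46) and Sesn2 of the stress and p53 list (0.33) higher. Of the imprinted list Plagl1 was higher (1.76) and Meg3 (-0.81) and Rian (-0.65) lower. The LIF and STAT3 list, with 3 genes higher and 4 lower, was called without ALSC 1 (camera adjusted p = 0.0483). The glycolysis list was called lower with the replicate block (0.0404) and without ABSC 1 (0.0347), and the stress and p53 list higher with the block (0.0214) and without ALSC 1 (0.0274). With the block both were lost with an estimated correlation (adjusted p = 0.613 and 0.551). Median and mean had opposite signs for the FGF and ERK (0.16 and -0.01) and imprinted (-0.08 and 0.04) lists, where camera took the sign of the median. Over all genes 875 were higher and 900 lower (1775), 223 and 461 of them at least 2-fold. With library size as the only scaling, 615 were higher and 1135 lower, so the share higher was 35.1% in place of 49.3%. The total was 4605 with the replicate block, 1041 in a fit of these 6 libraries alone, 846 without ABSC 2 and 958 without ABSC 3. Tmod1 (4.19) and A930004D18Rik (4.02) were among the genes most above ALSC in ABSC, and Slc39a4 (-3.69) among those most below it. A930004D18Rik was at 11 CPM in ABSC, 7.48 CPM in AFSC and 0.677 CPM in ALSC, so its difference lies mostly in ALSC. The primitive endoderm list had 2 genes higher and 4 lower, Sox17, Gata4, Gata6 and Pdgfra, and the WNT list 0 and 2. Sox17, at -5.907 to -4.175, held its call when each library was left out. In those fits Gata4 lost its call in 6, Gata6 in 2 and Pdgfra in 6.

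Changes shared by ABSC and ALSC against AFSC included higher Gdf3 (3.43 and 4.20), Hand1 (9.75 and 3.08) and Tdgf1 (0.49 and 0.75), and lower Sall2 (-0.63 and -0.67), Lef1 (-1.19 and -1.40) and Mdm2 (-0.74 and -1.20). In all 324 genes changed the same way, 143 higher and 181 lower, and 55 changed in opposite ways. Independent lists of these sizes would share 22.8 higher and 22.6 lower, and the simulations of unchanged groups against the shared controls gave 0, as groups without effects yield almost no calls, so that 0 does not measure how far shared controls raise the overlap. With the replicate block 1061 genes were shared, and 119 without AFSC 2, 111 without AFSC 3, 195 without ALSC 2, 188 without ALSC 3, 179 without ABSC 2 and 191 without ABSC 3. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.351, against 0.496 simulated from shared controls alone. The covariance was 0.0980 against 0.0432 simulated, a difference of 0.0548. The simulated libraries varied independently at the spread of the fit without a block, 0.147, while the block gave 0.0717. Deviations of number 1 shared by the groups cancel in the real differences, so the simulated covariance may be too high. Neither simulated value is a firm no-effect level, and 0.351 below 0.496 is not evidence against shared changes. The 3 AFSC libraries cannot be split into parts of at least 2, so part of the overlap may come from the shared controls.

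Genes that set 1 cell type at least 2-fold apart from both others, past the threshold in both comparisons, were most numerous for ABSC. ABSC had 106 such genes higher, Hand1, Evx1, Tmod1 and Nr5a2 among them, and 168 lower, among them Fgf5, Foxa2 and Gsc. ALSC had 110 higher, Socs3, Stat3 and Tfcp2l1 among them, and 34 lower, with Mllt10 among them. AFSC had 49 higher and 44 lower, with Gdf3 among the lower. With the replicate block the totals were 395 in place of 274 for ABSC, 243 in place of 144 for ALSC and 172 in place of 93 for AFSC. The ALSC total was 75 without AFSC 2 and 67 without AFSC 3. The AFSC total was 54 without AFSC 2, 44 without AFSC 3 and 62 without ABSC 2.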

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

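The tests for low-oxygen and amino-acid stress, for scatter of chromosome values and for overlapping reads, and the splits that keep the numbers paired, were chosen only after the result was seen.

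Genes were singled out here where their changes against AFSC differed between ABSC and ALSC by a test of that difference. In all 55 genes were called in opposite directions in the 2 cell types, and 245 with the replicate block. Among those chosen by the naming rule, higher in ABSC than in ALSC were Pou5f1 (log2 difference 0.39), Nr5a2 (4.65), Grhl2 (1.32), Id2 (4.18), Krt8 (1.21) and Klhl4 (3.16). Lower in ABSC were Kit (-1.69), Lefty2 (-2.62), Gsc (-4.40) and Slc39a4 (-3.69). The opposite calls against AFSC held in every fit without 1 library for Grhl2, Id2, Lefty2 and Slc39a4. Pou5f1 lost its ABSC call without any library but ALSC 1 (edgeR adjusted p 0.0514 to 0.193) and its ALSC call without any but ABSC 1 (0.0573 to 0.122). Kit lost its ABSC call without AFSC 3 (0.0535) and ABSC 2 (0.0516), and Gsc its ALSC call without AFSC 1 (0.0557), AFSC 2 (0.0699), AFSC 3 (0.0758) and ALSC 3 (0.0614). Klhl4 lost its ABSC call without AFSC 1 (0.0565), AFSC 2 (0.0636), ABSC 2 (0.0528) and ABSC 3 (0.0678), and Nr5a2 its ALSC call without AFSC 1 (0.0752), AFSC 2 (0.0772), AFSC 3 (0.0990), ALSC 1 (0.0640) and ALSC 2 (0.0787). Krt8 lost its ABSC call without AFSC 3 (0.0541), ABSC 2 (0.0569) and ABSC 3 (0.0525) and its ALSC call without AFSC 2 (0.0643), AFSC 3 (0.0536) and ALSC 3 (0.0522). Outside the genes used in the comparisons, 209 loci without a gene ID had more than 3 counts in each of the 9 libraries.

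The splits of the libraries were counted for each total. For each pair of groups only 10 splits exist, too few for a share under 0.05. The real split gave 1291 genes for ABSC against AFSC with at most 1 in another split, 1139 for ALSC against AFSC with at most 0, and 1775 for ABSC against ALSC with at most 0. For the test among 3 groups, 1 of 100 splits drawn, the real one, gave as many as 2395 genes, and these splits ignore the library numbers. Among the 36 splits with 1 library of each number in every group, the real one alone gave as many, with 2395 genes against at most 429, and with the replicate block 5992 against at most 636. The share, 0.0278, is the smallest that 36 splits can give, and these splits were chosen after the result was seen. It argues against a chance assignment within numbers but does not exclude it. Of the 100 drawn, the highest other split gave 1255 genes and put the 3 libraries numbered 1 together, which points to a structure of the samples.

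The libraries numbered 1 stood apart from numbers 2 and 3 in every group, with 5983 genes called, 3126 higher and 2857 lower. Removing each library's GC trend left 96.6% as many genes called (2723 higher, 3056 lower), 4817 of the 5983 in the same direction, and removing a gene length trend left 101%, with 5604, which argues against either trend as the whole cause. Genes of low-oxygen and amino-acid stress, 31 of 32 tested, were higher in number 1 by a median log2 of 0.34 in AFSC, 0.63 in ALSC and 0.43 in ABSC. Of these genes 26 were called higher and 0 lower, with P4ha1 at 1.11 and Asns at 0.75. Ccng2 (2.27), Chac1 (2.45) and Ddit4 (2.03) were also higher but are not among the listed genes. A shared culture state such as denser or older medium is a candidate explanation for these genes. The labels give no date or batch, so a handling batch stays open, and no biological difference between the numbers is named by the design.

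Genes of chromosomes 8 and 11 were slightly higher in ALSC than in AFSC, by median shifts of 0.05 and 0.09 on the log2 scale (1.034-fold and 1.065-fold), against -0.04 to 0.04 on the other 17 autosomes, where chromosome 18 at 0.0436 came close to chromosome 8. The share of 10000 shuffles of genes over chromosomes with shifts as large was 1e-04 for both, the smallest they can give, although genes on a chromosome are not independent. Both shifts stayed after the GC trend was removed, at 101% or more of their size, which argues against GC content as the whole cause. An extra copy in a share of the cells may explain them, since all 8 stretches, 4 per chromosome with about as many genes each, were shifted up. On chromosome 8, however, they were at 0.0555 (SE 0.0355), 0.0747 (SE 0.0496), 0.0357 (SE 0.0396) and 0.0681 (SE 0.029) in order of position. The lowest lies within its error, and the first and second lie little beyond theirs. While chromosome 11 was shifted in each ALSC library (0.0799 to 0.122), chromosome 8 (0.0437 to 0.0619) lay below chromosomes 18 (0.0579) and 13 (0.0447) in ALSC 3. Regulation in LIF stays open, as does passage, which differs with the group, and copy number was not measured.

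On chromosome 2, 3 neighbouring genes were lower in ALSC: A930004D18Rik (-3.45, 18025193 to 18037737), Skida1 (-5.50, and -6.44 without ALSC 3; 18040676 to 18049051) and Mllt10 (-1.82, 18055237 to 18212388), while Dnajc1 (-0.08) and Commd3 (-0.00) on 1 side were not called. Plxdc2, the nearest tested gene on the other side, was also lower (-0.57, edgeR adjusted p = 0.0185), and beyond Commd3 Bmi1 (-0.66, 0.0536) and Etl4 (-0.38, 0.0513) leaned lower, so the loss may reach past the 3 genes. The 3 genes do not overlap each other, so reads shared between them cannot explain the loss. The ratio tested, 45.8 CPM lost by Mllt10 over 12.3 CPM of the other genes in AFSC (3.74), therefore adds nothing. Mllt10 does overlap Dnajc1, which was at 17.2 ± 1.26 CPM in AFSC and 16.2 ± 1.89 CPM in ALSC. A run of 3 or more such neighbours among the 146 genes at least 2-fold lower arose in 0.013 of 10000 shuffles of gene order, which argues against unrelated neighbours. A change of the locus in the ALSC cells, genetic or regulatory, may be the cause, which stays open and untested, as does the RNA kit.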

How the results depend on the processing

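The fit of libraries 2 and 3 only, the block of number 1, and the GC correction with the block were chosen only after the result was seen. In the order ABSC against AFSC, ALSC against AFSC, ABSC against ALSC, any difference, and changes shared by ABSC and ALSC, the fit without a block called 1291, 1139, 1775, 2395 and 324 genes. The replicate block called 3132, 3590, 4605, 5992 and 1061, libraries 2 and 3 only 4622, 4122, 5225, 7121 and 1657, the block of number 1 3457, 3977, 4994, 6521 and 1212, and the GC correction with the block 3149, 3557, 4760, 6099 and 1029. The coefficient of variation was 0.0717 with the replicate block in place of 0.147. For the other fits the cause was not tested, but libraries 2 and 3 are the closest pair of each group. Of the first 3 totals, 1284, 1132 and 1771 genes were called in the same direction with and without that block. Testing against a 2-fold change called 121, 45 and 143, with 10 shared, as a stricter hypothesis must. The 6 libraries alone gave 1041 genes for ABSC against ALSC, with fewer samples. DESeq2 called 1657, 1614, 2223, 3152 and 478, and RLE size factors 1301, 1135 and 1809 in the first 3.

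For genes setting 1 type apart, in the order ABSC, ALSC and AFSC, the totals 274, 144 and 93 became 395, 243 and 172 with the replicate block, 57, 19 and 10 against a 2-fold change, 458, 256 and 234 in libraries 2 and 3 only, 255 and 185 for ALSC and AFSC with the block of number 1, and 242 and 170 with the GC correction and block. Leaving out 1 library at a time gave 667 to 1723 genes for ABSC against AFSC, 345 to 1522 for ALSC against AFSC, 846 to 2337 for ABSC against ALSC, 1395 to 3048 for any difference and 111 to 442 shared, and 186 to 365, 67 to 169 and 44 to 121 for genes apart. Totals were lowest without AFSC 3 in both comparisons with AFSC and without ABSC 2 in the third.

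Camera called 18 of 72 list tests, 2 with an estimated correlation, 38 by fry, 27 without a filter on low counts, and 17 to 21 when 1 library was left out. Without that filter the naive pluripotency list in ALSC against AFSC was called (camera adjusted p = 0.0351 in place of 0.291). Over all settings list results were the same in 1201 cases, gained a call in 62, lost it in 33 and reversed in 0. Of single named genes, 3814 results were the same, 418 lost the call, 40 gained it and 1 reversed. That was T in ABSC against ALSC, uncalled at -0.12 but higher in libraries 2 and 3 only (0.16, edgeR adjusted p = 0.0157). That fit leaves out ABSC 1, at 72.2 CPM, together with AFSC 1 and ALSC 1, and the cause was not tested. Without a filter on low counts Cdx2 in ABSC against AFSC had an edgeR adjusted p of 0.0660; the cause was not tested. The replicate block removed the calls of Fgf8 (edgeR adjusted p = 0.0540) and T (0.0708) in ALSC against AFSC and Cdkn1c in ABSC against ALSC (0.0907). It added Gata6 (0.00161), Socs3 (0.0236) and Vim (0.00450) in ABSC against AFSC, Gata6 in ALSC against AFSC (0.0156) and Sox2 in ABSC against ALSC (0.0103), and changed no other call of a named gene, nor of a list beyond the 7 given with their comparisons. Elf5, at 0.0332 CPM in ABSC, lay below the floor of 0.138 to 0.157 CPM per library and was not tested.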

Other observations

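The genes named in this part, the homeobox test and the interest in chromosome 12 were chosen only after the result was seen. Several signalling and metabolic genes set 1 cell type apart. In ABSC the creatine kinase gene Ckb stood at 176 ± 13.9 CPM against 64.3 ± 2.09 CPM in AFSC (log2 fold change 1.46, edgeR adjusted p = 4.19e-06), the chemokine gene Cxcl12 at 120 ± 14.5 CPM against 28.8 ± 2.77 CPM (2.06), and the cyclin gene Ccnd2 rose by 2.09. Eras, a Ras gene of embryonic stem cells, was lower in ABSC, at 9.91 ± 1.00 CPM against 36.6 ± 3.34 CPM (-1.88, edgeR adjusted p = 1.09e-05), with the imprinted gene Nnat (-2.14) and the streak ligand gene Wnt8a (-2.23). In ALSC the uridine phosphorylase gene Upp1 stood at 226 ± 44.2 CPM against 55.3 ± 7.30 CPM in AFSC (2.04, edgeR adjusted p = 0.000110), and the guidance gene Sema3e was lower (-1.34). The helicase gene Mov10 was higher in both, by 1.01 in ABSC and 1.20 in ALSC, and the noncoding gene Platr10 lower in both, by -1.35 and -1.11.

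Part of a list of interferon response genes was higher in ALSC than in AFSC. Interferon-linked genes already seen higher in these data prompted the list, which was meant to hold only genes not seen before. Of 41 listed genes 30 were tested, and 11 rose and 0 fell (16 and 0 adjusted over the list alone), with Zbp1 at a log2 fold change of 3.30. The list's median change was 0.66 (camera adjusted p = 3.33e-09, adjusted over 3 comparisons). That call was lost at adjusted p = 0.0503 with an estimated correlation. Each ALSC library stood above the AFSC mean, with medians of 0.62 to 0.71. With the preset correlation it held in every fit without 1 library (camera adjusted p 1.64e-10 to 2.51e-07), with 5 genes higher without AFSC 2 or AFSC 3 and 5 to 13 over all such fits. A coordinated interferon-like state in ALSC, which LIF acting through STAT proteins could give, is a hypothesis that this test leaves open, along with passage and the RNA kit. In ABSC the list showed no rise as a whole, with a median of -0.00 (SE 0.14, camera adjusted p = 0.792, and 0.0684 without ABSC 1). A median at or below 0 had been set beforehand as the outcome against a coordinated rise. That outcome was met, but only within the error of the median. There 1 gene rose and 1 fell against AFSC, and 5 and 5 with the replicate block. The list was meant to leave out interferon-linked genes already seen higher in ABSC, so these counts do not cover them. Between ABSC and ALSC 10 of the genes were lower in ABSC and 0 higher (camera adjusted p = 3.38e-08; adjusted p = 0.0503 with an estimated correlation).

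Homeobox genes were frequent among the 274 genes that set ABSC apart. They made up 10 of the 274 (3.65%) against 0.340% of the other tested genes, an odds ratio of 11.1 (95% interval 4.99 to 22.3, Fisher's exact test p = 1.12e-07). In ABSC 7 were higher, Cdx2, Evx1, Mnx1, Msx1, Msx2, Meis1 and Meis2, and 3 lower, Gsc, Lhx1 and Mixl1. Leaving out 1 library at a time gave odds ratios of 9.97 to 15.1, and the replicate block 10.5 with 13 genes. A different homeobox gene make-up of ABSC, with genes gained and lost, may underlie this, as a hypothesis found and tested on the same data.

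Chromosome 12 genes had a median shift of 0.0437 on the log2 scale in ABSC against AFSC, with a shuffle share of 1e-04, the smallest the shuffles can give, although genes on a chromosome are not independent. The other 18 autosomes had shifts of -0.0212 to 0.0353, and in ABSC 2 and ABSC 3 chromosome 18 (0.0458 and 0.0490) exceeded chromosome 12 (0.0344 and 0.0350). The glycolysis gene Gapdh varied widely between libraries of the same group, at 52.9, 385 and 383 CPM in AFSC, 237, 297 and 83.5 CPM in ALSC and 111, 67.0 and 246 CPM in ABSC.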
